A study of Homo sapiens with 18 samples.

How the data were processed

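The analysis used the deposited processed table of 18 Affymetrix human gene expression arrays and the sample labels. The deposited values were treated as log2 MAS5 signals. MAS5 is named in the submitters' processing notes, and the log base was inferred from the values, because 2 raised to the deposited values gave a trimmed mean (2% trimmed) from 100.122 to 100.134 in every array, with a 5% difference allowed. The deposited values ran from -5.83 to 13.0, with 9.38% below 0 and array medians from 4.30 to 4.56. Raw array files were not used here.

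The arrays made 9 groups of 2: untransfected cells (Control), cells given a negative-control siRNA (siNeg) and cells given an siRNA against MPS1 (siMPS1), at 6, 24 and 48 h. Per the labels, 2 pmol of siRNA was used for transfection and 250 ng of total RNA was labelled with biotin. The siRNA sequences, the transfection reagent and the meaning of the replicate numbers are not given in the sources used here. Replicate arrays correlated from 0.983 to 0.990 and 0 pairs were identical.

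The table held 22277 probe sets, of which 62 were controls of the array. Of the other 22215, 19064 named exactly 1 gene, 1043 named several and 2108 had no gene in the annotation table. Probe sets naming exactly 1 gene were kept, and 19052 of them matched the RefSeq gene table by identifier, with 0 symbols changed. Genomic coordinates were not used. The 40% of probe sets with the lowest mean were left out, and the probe set with the highest mean was kept for each gene, leaving 7828 genes.

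Signals were returned to the linear scale, a pseudocount of 3 (the 20th percentile of the signals) was added, and log2 was taken. No further normalization between arrays was applied in the chosen fit. Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with 9 residual degrees of freedom, moderated variances with an intensity trend and a prior of 8.57 degrees of freedom. Tests were two-sided. The contrasts were siMPS1 minus siNeg, siNeg minus Control and siMPS1 minus Control at each time, siMPS1 minus siNeg averaged over the times, the difference of siMPS1 minus siNeg between successive times, and Control between successive times. Adjusted p-values follow Benjamini and Hochberg within each contrast, and a gene was called at an adjusted p under 0.05.

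Gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated from the data, with adjustment over all lists and times of a family of contrasts. The 24 lists were written from general knowledge and covered the spindle checkpoint and kinetochore, mitosis and G2/M, G1/S and replication, histones, p53 targets, DNA repair, apoptosis, interferon-induced genes, NF-kB and inflammation, ER stress and ATF4, sterol synthesis, hypoxia and glycolysis, immediate early genes, YAP targets, extracellular matrix and TGF-beta, glial and astrocyte genes, neuronal genes, epithelial markers, blood markers, oxidative phosphorylation, ribosomal proteins, the proteasome, autophagy and lysosome, and the RNA interference machinery. Lists with fewer than 5 measured members were not tested. For each list the members called over all genes and those with an adjusted p under 0.05 adjusted over the list alone were counted.

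The sample groups, contrasts, most alternatives and lists were chosen before the data were examined. Genes were named by a rule. TTK was always named. For siMPS1 minus siNeg at each time the 10 called genes with the largest rise and the 10 with the largest fall were taken among those in which both siMPS1 arrays lay beyond both siNeg arrays, and 5 in each direction were taken for siNeg minus Control, the average and the differences between times. For the differences between times the criterion on single arrays was not applied. For each described list the 4 members with the smallest p were named.

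The alternatives were pseudocounts of 1 (5th percentile) and 11 (40th percentile), quantile normalization, median centring, no filter, leaving out the lowest 60% of probe sets, averaging the probe sets of a gene, no intensity trend, a replicate block, an estimated correlation for lists, only the compared groups in the fit, a fold change of at least 2 as well, counting probe sets instead of genes, and leaving out each of the 18 arrays in turn. A count was taken as moved when it changed by more than 1.5 times. Added after the data were seen were an average and all-time counts without 48 h, counts of genes also called in the same direction against Control, and the difference of siMPS1 minus siNeg between 6 and 48 h for TTK.

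Overlaps between contrasts were compared with independent calls and with 50 simulations without change that kept the design and the shared arrays. Such simulations call almost no genes, so their small overlaps do not measure what shared arrays add to real changes. The average contrast was compared with 100 splits of the 12 transfected arrays. Checks of control probe sets used the log2 ratios of 3' to 5' signals of ACTB and GAPDH, the spikes, 18S rRNA and Alu probe sets.

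The code was tested on simulated data with the design of siMPS1 minus siNeg at 6 h, 7832 genes and 200 changed genes. It recovered 50.7% of 67 genes changed 1.5-fold, 83.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold. It called 178 genes, of which 153 were changed genes in the true direction, 17 were members of a list of 40 other genes shifted by 0.4, and 8 were unchanged, and it called 0 genes when none was changed. The shifted list was called, and 0 of 20 unchanged lists were. Genes were simulated independently of each other, so the list test was not tried on correlated genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.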

Results

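TTK, the gene of the spindle checkpoint kinase MPS1, fell in siMPS1 cells at every time measured. U251, an established human glioblastoma line, was compared as untransfected cells (Control), cells given a negative-control siRNA (siNeg) and cells given an siRNA against MPS1 (siMPS1), at 6, 24 and 48 h, with 2 arrays per group. At 6 h the mean TTK log2 signal was 4.17 in siMPS1 (SD 0.14, n = 2), 5.60 in siNeg (SD 0.17) and 5.53 in Control (SD 0.27). At 24 h it was 4.99 in siMPS1 (SD 0.34), 6.87 in siNeg (SD 0.02) and 6.97 in Control (SD 0.22), and at 48 h it was 4.52 (SD 0.37), 6.82 (SD 0.14) and 6.74 (SD 0.24).

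Against siNeg, the TTK log2 fold change was -1.43 at 6 h (adjusted p = 0.000804), -1.88 at 24 h (adjusted p = 8.8e-06) and -2.30 at 48 h (adjusted p = 2.33e-07), each with an SE of 0.21 in limma. With the pseudocount of 3 included, the signal left was 37.1%, 27.1% and 20.3% of that in siNeg. Against Control the changes were -1.36, -1.98 and -2.22, with adjusted p of 0.000531, 5.12e-06 and 5.48e-07. Between siNeg and Control, TTK differed by 0.07, -0.10 and 0.08 (adjusted p = 0.897, 0.887 and 0.859). The change in the TTK response from 6 to 24 h was -0.45 (adjusted p = 0.42) and from 24 to 48 h -0.41 (adjusted p = 0.379), neither of which passed the test. The change from 6 to 48 h, tested after the data were seen, was -0.87 (SE 0.29, adjusted p = 0.0421). The siMPS1 mean itself did not fall, being 4.17 at 6 h and 4.52 at 48 h, while that of siNeg rose from 5.60 to 6.82. Both deposited siMPS1 values at 6 h (3.78 and 4.02) lay under their array medians (4.52 and 4.56). At 48 h siMPS1 replicate 2 did too (4.01 against 4.43). Such dim signals can compress a fold change, so these values do not show silencing that deepened with time. TTK ranked 18, 37 and 69 by p among 7828 genes at the successive times. Whether the 2 arrays of a group came from separate transfections is not given in the sources used here, so every p-value measures only the spread between these samples, and their number limits the precision.

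**Figure D1:**
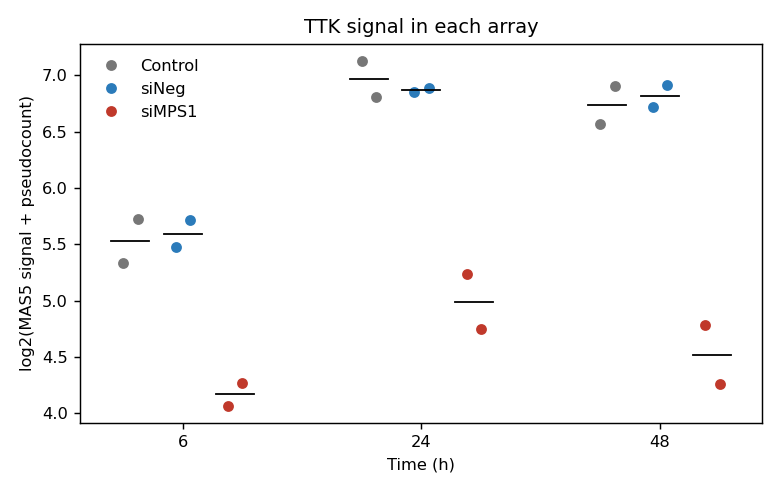
TTK signal (log2 of MAS5 signal plus a pseudocount of 3) in each array by time after transfection in h; points are arrays, black lines are means of 2 arrays, and colours mark Control, siNeg and siMPS1. Both siMPS1 arrays lay below all siNeg and Control arrays of their time.

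At 6 h, siMPS1 cells had less MSMO1, an enzyme of cholesterol synthesis, than siNeg cells, by a log2 fold change of -1.33 (SE 0.08, adjusted p = 1.16e-08). In this and every other gene named for its size of change against siNeg at a given time, both siMPS1 arrays lay beyond both siNeg arrays. AGTPBP1, a carboxypeptidase that trims tubulin tails, fell by 1.21 on the log2 scale (SE 0.22, adjusted p = 0.00577). PCCA, a subunit of propionyl-CoA carboxylase, and CLCN4, a chloride and proton exchanger, fell by 1.62 and by 1.12. Each of these fell against Control as well, with -1.27 for MSMO1, -0.90 for AGTPBP1, -1.34 for PCCA and -1.56 for CLCN4. DDX3Y, an RNA helicase gene, fell by 1.13 (SE 0.16, adjusted p = 0.000548) and was also called lower against Control (adjusted p = 0.000629). PACSIN3, a protein of membrane bending, was at -1.19 against siNeg and at -0.81 against Control (adjusted p = 0.0481). NFKBIL1, PLEKHG3 and LRAT changed by -1.58, -1.54 and -1.32 against siNeg, and passed no test against Control.

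The named genes that rose at 6 h were dim, with mean log2 signals from 3.72 for BCAS3 to 4.68 for ACTC1. Among the named falls, CLCN4 (3.96), LRAT (4.19), PLEKHG3 (4.21), PCCA (4.39) and NFKBIL1 (4.47) were as dim. The named rises at 6 h are given next. These rises were led by MINDY1, a deubiquitinase, with a log2 fold change of 2.07 (SE 0.45, adjusted p = 0.013), BCAS3 with 1.59 and the transcription factor KLF12 with 1.32. INAVA rose by 1.30 against siNeg and by 1.02 against Control. ADTRP, PIK3R5, MKS1, PADI1, ACTC1 (cardiac actin) and HDAC7 (a histone deacetylase) rose by 1.25, 1.21, 1.17, 1.17, 1.13 and 1.11. Apart from INAVA, none of these named rises passed the test against Control, where MINDY1 was 0.43 and KLF12 0.44. Without an intensity trend in the variance, MINDY1, BCAS3, INAVA, ADTRP, PADI1, ACTC1 and HDAC7 lost their call, and with only the compared groups in the fit so did KLF12 and PIK3R5. MKS1 lost its call without the filter on dim probe sets, and so did PCCA and NFKBIL1. Of the genes named at 6 h only TTK, MSMO1 and DDX3Y kept their call whichever array was left out, and each of the others lost it without 1 or more of siNeg 6 h replicates 1 and 2 and siMPS1 6 h replicates 1 and 2.

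Among the gene lists at 6 h, the ribosomal protein genes were higher in siMPS1 than in siNeg, with 15 of 32 measured members up and 0 down (22 up and 0 down adjusted over the list alone) and a median log2 fold change of 0.23, which shrank to 0.01 under quantile normalization (adjusted p = 0.908). RPL29, RPL3, RPS6 and RPL12 rose by 0.41, 0.45, 0.46 and 0.52. The list call had an adjusted p of 5.87e-12, against an adjusted p = 0.259 with an estimated correlation. Genes of oxidative phosphorylation were called up with 7 of 38 members up and 0 down (10 and 0 adjusted over the list alone, adjusted p = 4.78e-05). COX7C, COX4I1 and COX7B, subunits of cytochrome c oxidase, rose by 0.34, 0.28 and 0.25, and SDHC of succinate dehydrogenase by 0.48. That call had an adjusted p = 0.0625 with an estimated correlation. Proteasome genes were called up with 6 of 26 members up and 0 down (7 and 0 adjusted over the list alone, adjusted p = 0.00159), among them PSMA1, PSMA7, PSMB3 and PSMB6 with 0.35, 0.29, 0.26 and 0.24. Here the adjusted p was 0.126 with an estimated correlation. Neither list was called against Control at 6 h (adjusted p = 0.483 for oxidative phosphorylation and 0.986 for the proteasome, medians 0.07 and 0.02), and both were called lower in siNeg than in Control, calls that ended with an estimated correlation (adjusted p = 0.173 and adjusted p = 0.109) and under quantile normalization.

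The mitotic and G2/M list was called down at 6 h (adjusted p = 0.0463, median -0.030), with 1 of 43 members up and 7 down (2 and 9 adjusted over the list alone). The list had an adjusted p = 0.0915 with an estimated correlation, and its adjusted p ranged from 0.00643 to 0.163 over 11 alternatives, 5 of which kept the call. Leaving out siNeg 6 h replicate 1, siMPS1 6 h replicate 2 or any siNeg or siMPS1 array of 24 h also ended it, with adjusted p up to 0.147. ECT2, which drives cytokinesis, fell by 0.50, the spindle motor gene KIF11 by 0.49, CCNB1 by 0.37 and CCNA2 by 0.61, the last pair being mitotic cyclins. CDC25B, a phosphatase that activates the cyclin-dependent kinases, rose by 0.51 and was named after its value was seen. Against Control the list was not called at 6 h (adjusted p = 0.104). In the siMPS1 arrays of 6 h the Alu signal was 12.96 on the log2 scale, against 12.48 in siNeg and 12.42 in Control. The 18S rRNA signal was 10.36 against 10.08 and 10.16, and the dap spike 6.27 against 6.57 and 7.21. Genes called between siMPS1 and siNeg at 6 h numbered 603 of 7828, 270 higher and 333 lower. After median centring of the arrays 151 were higher and 339 lower, and after quantile normalization 236 and 325. The count was 110 without either siNeg 6 h array and 80 without siMPS1 6 h replicate 2, and 388 without the filter on dim probe sets or 169 without the intensity trend.

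At 24 h, genes of the extracellular matrix and of TGF-beta signalling were higher in siMPS1 than in siNeg. LAMC1, a laminin chain, rose by 0.59, the basement membrane collagens COL4A1 and COL4A2 by 0.70 and 0.63, and the proteoglycan gene VCAN by 0.64. Of 32 measured members 10 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.27 and an adjusted p of 0.000101 (adjusted p = 0.0116 with an estimated correlation). The member that fell, named after its value was seen, was COL6A2, a chain of collagen VI, with -0.51.

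Lysosomal and autophagy genes were lower at 24 h. NPC2, which carries cholesterol out of lysosomes, fell by 0.79, the sialidase gene NEU1 by 0.67, ATG12 of the autophagy conjugation system by 0.53 and the lysosomal peptidase gene TPP1 by 0.40. In this list 0 of 27 members rose and 6 fell (0 and 10 adjusted over the list alone, median -0.17, adjusted p = 0.000195, and adjusted p = 0.0139 with an estimated correlation). Against Control the list was not called (median -0.06, adjusted p = 0.0955), and it was called higher in siNeg than in Control, a call that ended with an estimated correlation (adjusted p = 0.115) and under quantile normalization. Sterol synthesis genes were lower too, with 0 of 19 up and 5 down over all genes and over the list alone (median -0.20, adjusted p = 0.000666, and adjusted p = 0.0245 with an estimated correlation). MSMO1 fell by 1.40 (SE 0.08, adjusted p = 1.11e-09), while the desaturase gene SC5D, the sterol sensor INSIG1 and the epoxidase gene SQLE fell by 0.36, 0.45 and 0.27. Genes of the ER stress and ATF4 response were lower, with 0 of 33 up and 6 down (0 and 10 adjusted over the list alone, median -0.14, adjusted p = 0.000258, and adjusted p = 0.0253 with an estimated correlation). The stress transcription factor ATF3 fell by 0.52, the phosphatase subunit gene PPP1R15A by 0.42, and CTH and PSAT1, enzymes of cysteine and serine synthesis, by 0.65 and 0.70.

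DNA replication and G1/S genes were higher at 24 h, with 11 of 41 up and 2 down (16 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.0011), a call that ended with an estimated correlation (adjusted p = 0.0915). The replicative helicase genes MCM6 and MCM3 rose by 0.82 and 0.55, the uracil glycosylase gene UNG by 0.59 and RRM1, a subunit of ribonucleotide reductase, by 0.47. The members that fell, named after their values were seen, were the cyclin E genes CCNE1 and CCNE2, with -0.54 and -0.75.

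Among single genes at 24 h, NREP rose by 1.29 (SE 0.12, adjusted p = 1.58e-06) and IL1RAP, a co-receptor for interleukin-1, by 1.73 (SE 0.32, adjusted p = 0.00165), and both rose against Control, by 1.23 and 1.03. FGF1, a fibroblast growth factor, rose by 1.57 and ABCA1, a cholesterol exporter, by 1.16. FRS3, DUSP26, C2orf68 and LGR5 were dim (mean log2 signals 3.90, 3.87, 4.12 and 3.96) and rose by 1.51, 1.49, 1.38 and 1.34. PPP4R3B and PLEKHO2 rose by 1.21 and 1.19. None of FRS3, DUSP26, C2orf68, LGR5, PPP4R3B, PLEKHO2, FGF1 and ABCA1 passed the test against Control. All 8 also lost their call with only the compared groups in the fit, and apart from FGF1 each lost it without at least 1 of siNeg 24 h replicates 1 and 2 and siMPS1 24 h replicates 1 and 2. JPT1 fell by 1.43 (SE 0.06, adjusted p = 2.09e-10), VAPA, a tether between the ER and other membranes, by 1.31 (SE 0.06, adjusted p = 2.09e-10), and SSR3 of the ER translocon by 1.61 (SE 0.13, adjusted p = 1.62e-07). SEPTIN10, a septin, fell by 1.39, the adenosine receptor gene ADORA2B by 1.33, CHMP2B of the ESCRT machinery by 1.29 and the transcription factor gene TBX2 by 1.47. Against Control these 7 changed by -1.33, -1.19, -1.24, -1.01, -1.21, -1.09 and -1.38, in the order given, and all were called. SCAMP4 changed by -1.34 and was not called against Control or after quantile normalization. TBX2 lost its call without siNeg 24 h replicate 2 or siMPS1 24 h replicate 2, and SCAMP4 without these or siNeg 24 h replicate 1.

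Genes called between siMPS1 and siNeg at 24 h numbered 857, of which 402 were higher and 455 lower. The count was 361 without siNeg 24 h replicate 1, 453 without siNeg 24 h replicate 2, 424 without siMPS1 24 h replicate 2, and 502 with only the compared groups in the fit. The 18S rRNA signal of the siNeg arrays of 24 h was 11.15 on the log2 scale, against 10.36 in siMPS1 and 10.18 in Control.

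At 48 h, mitotic and spindle checkpoint genes were lower in siMPS1 than in siNeg. PLK1, a mitotic kinase, fell by 1.79 (SE 0.18, adjusted p = 7.02e-07), the checkpoint gene BUB3 by 0.66, and the kinetochore genes CENPU and SPC25 by 0.77 and 0.99. CCNB2 and CCNB1, the B-type cyclins, fell by 1.41 and 0.77, PRC1 of the central spindle by 0.84, and UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, by 0.84. In the checkpoint and kinetochore list 0 of 30 members rose and 19 fell over all genes and over the list alone (median -0.38, adjusted p = 4.76e-09, and adjusted p = 0.00165 with an estimated correlation). In the mitotic and G2/M list 1 of 43 rose and 28 fell (1 and 29 adjusted over the list alone, median -0.41, adjusted p = 3.55e-11, and adjusted p = 0.00139 with an estimated correlation). The member that rose, named after its value was seen, was CDC25B with 0.31.

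The fall of both lists was also called against Control at 48 h. There the checkpoint list had 1 member up and 10 down (median -0.16, adjusted p = 0.00183, and adjusted p = 0.0454 with an estimated correlation), and the mitotic list 3 up and 20 down (3 and 22 adjusted over the list alone, median -0.25, adjusted p = 9.55e-05, and adjusted p = 0.0377 with an estimated correlation). CCNB2 fell by 1.21, CCNB1 by 0.60, BUB3 by 0.58, CENPN by 0.68, CENPF by 0.61, SPC25 by 0.78, PRC1 by 0.50 and UBE2C by 0.53, while PLK1 fell by 0.65. The members that rose against Control, named after their values were seen, were BUB1B (0.34) in the first list and KIF18B (0.48), CDC25B (0.70) and FOXM1 (0.53) in the second.

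Replication and G1/S genes were lower at 48 h against siNeg, with 1 of 41 up and 17 down (1 and 19 adjusted over the list alone, median -0.24, adjusted p = 1.12e-05, and adjusted p = 0.0311 with an estimated correlation). Those that fell included RFC3 of the clamp loader (-0.997), CCNE2 (-1.28), the primase gene PRIM1 (-0.88) and the thymidylate synthase gene TYMS (-0.45). DNA repair genes were lower, with 1 of 26 up and 10 down (1 and 12 adjusted over the list alone, median -0.23, adjusted p = 0.0017, and adjusted p = 0.0381 with an estimated correlation). H2AX, the histone variant phosphorylated at DNA breaks, fell by 0.68, FANCI by 0.57, RPA3 by 0.46 and RAD51AP1 by 0.66. The members that rose, named after their values were seen, were the chromatin assembly gene CHAF1A (0.39) and PALB2 (0.66), the partner of BRCA2. Neither list was called against Control (adjusted p = 0.177 and 0.0668).

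Genes of the ER stress and ATF4 response were higher at 48 h against siNeg, with 23 of 33 up and 4 down (24 and 6 adjusted over the list alone, median 0.42, adjusted p = 6.33e-07, and adjusted p = 0.0098 with an estimated correlation). DDIT3, a stress transcription factor, rose by 1.12, HERPUD1 of ER-associated degradation by 0.83 and the chaperone gene DNAJB9 by 0.70. PSAT1, of serine synthesis, fell by 1.60, and PPP1R15A, PDIA6 and MTHFD2, the last 3 named after their values were seen, changed by -0.41, -0.26 and -0.26. Autophagy and lysosomal genes were higher, with 12 of 27 up and 1 down over all genes and over the list alone (median 0.22, adjusted p = 0.0017, and adjusted p = 0.0253 with an estimated correlation). WIPI1, SQSTM1 and NPC1 rose by 0.89, 0.46 and 0.48, while NPC2 fell by 0.67. Against Control these lists had adjusted p of 0.466 and 0.514, with DDIT3 at 0.33 and HERPUD1 at 0.18.

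The NF-kB and inflammation list was called up at 48 h against siNeg, with 10 of 24 up and 2 down (12 and 2 adjusted over the list alone, median 0.37, adjusted p = 0.0203). The collagenase MMP1 and the stromelysin MMP3, matrix-degrading enzymes, rose by 1.23 and 1.57 and the cytokine gene IL11 by 0.54, while the chemokine gene CCL2 fell by 1.15 and PLAU, a plasminogen activator named after its value was seen, by 0.30. Its adjusted p was 0.0654 with an estimated correlation, from 0.00982 to 0.0858 over 11 alternatives, and 0.0538 without siMPS1 48 h replicate 2. Against Control the list was not called (median 0.09, adjusted p = 0.84), and it was lower in siNeg than in Control. The ribosomal list was called down (adjusted p = 0.035, median -0.08), with 0 of 32 up and 4 down (0 and 1 adjusted over the list alone). RPL10A, RPL18, RPS7 and RPL6 fell by 0.30, 0.22, 0.18 and 0.19. This call had an adjusted p = 0.713 with an estimated correlation, ended under quantile normalization, and reached an adjusted p of 0.529 when 1 array was left out, being lost without siNeg 48 h replicate 1 or siMPS1 48 h replicate 1, and the list was not called against Control (adjusted p = 0.177).

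The largest single rises at 48 h were those of RASSF8 (2.14, SE 0.35, adjusted p = 0.000172), HMOX1 (2.06, SE 0.08, adjusted p = 5.68e-12), AKR1C1 (1.84, adjusted p = 2.08e-09) and GDF15 (1.82, adjusted p = 1.66e-10). HMOX1 encodes heme oxygenase, AKR1C1 an aldo-keto reductase and GDF15 a stress-induced cytokine. Against Control, HMOX1 rose by 0.40, AKR1C1 by 0.42 and GDF15 by 0.65, and RASSF8 was 0.39 and not called. CPEB1, DHRS9, G0S2, SPINK1 and DEPP1 rose by 1.72, 1.68, 1.65, 1.58 and 1.58 against siNeg and were not called against Control. TAOK1, a stress-responsive kinase, rose by 1.57 against siNeg and by 0.99 against Control. TAF9B, a subunit of transcription initiation complexes, fell by 2.29 (SE 0.12, adjusted p = 4.16e-10), with 1 of 2 other probe sets past the filter of the opposite sign, and DDA1, ADORA2B, the homeobox gene HOXB3 and PRAF2 were at -2.04, -1.76, -2.30 and -1.75. Against Control these 5 were at -1.95, -1.48, -1.74, -1.61 and -1.04. PTMS, HTR4 and POLM changed by -2.28, -1.97 and -1.77 against siNeg and were not called against Control. Leaving out siNeg 48 h replicate 1 ended the calls of CPEB1, HTR4, G0S2, DEPP1 and POLM, siMPS1 48 h replicate 1 those of CPEB1 and HTR4, and siNeg 48 h replicate 2 or siMPS1 48 h replicate 2 that of POLM.

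Genes called between siMPS1 and siNeg at 48 h numbered 2284, of which 1231 were higher and 1053 lower, and 1293 of them were called in the same direction against Control. In the siMPS1 arrays of 48 h the log2 ratio of ACTB 3' to 5' control signals, a measure of RNA integrity, was 0.90 (SD 0.04), against 0.12 (SD 0.03) in siNeg and 0.20 (SD 0.06) in Control.

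**Figure D2:**
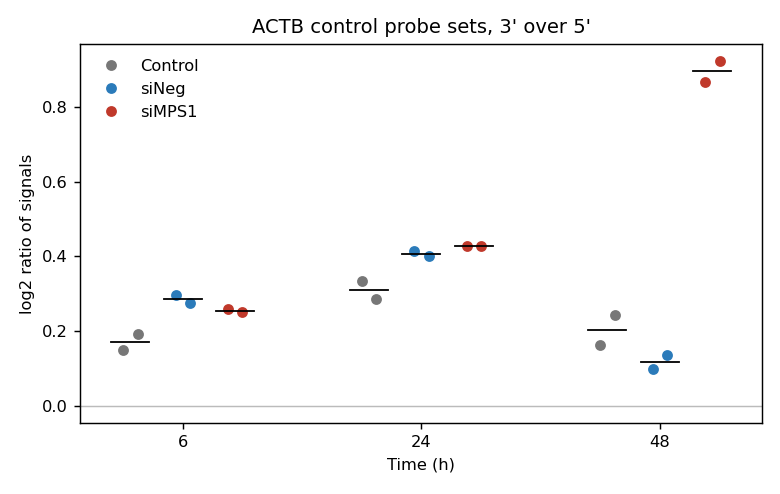
Log2 ratio of the signals of the ACTB 3' and 5' control probe sets in each array by time in h, with points for arrays and black lines for means of 2. The siMPS1 arrays of 48 h averaged 0.90 and all other arrays lay at or under 0.43.

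Of the gene lists, 10 passed no test between siMPS1 and siNeg at any time. The p53 target list had adjusted p of 0.537, 0.729 and 0.397 at the successive times. At 48 h 6 of its 22 members rose and 2 fell, among the former CDKN1A, an inhibitor of cyclin-dependent kinases, by 1.47 against siNeg and by 1.06 against Control. Apoptosis genes had adjusted p of 0.888, 0.686 and 0.882, histone genes 0.686, 0.747 and 0.912, interferon-induced genes 0.686, 0.662 and 0.974, and hypoxia and glycolysis genes 0.283, 0.394 and 0.974. The values were 0.398, 0.0658 and 0.155 for immediate early genes, 0.974, 0.894 and 0.57 for YAP targets, 0.397, 0.934 and 0.298 for glial and astrocyte genes, 0.508, 0.747 and 0.974 for neuronal genes, and 0.278, 0.769 and 0.974 for the genes of the RNA interference machinery. The median and the mean or the tested direction differed in sign, all in uncalled tests, for ER stress and YAP targets at 6 h, for checkpoint, apoptosis, YAP and RNA interference genes at 24 h, and for hypoxia, neuronal and RNA interference genes at 48 h. Epithelial and blood marker lists had 4 measured members each and were not tested.

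**Figure D3:**
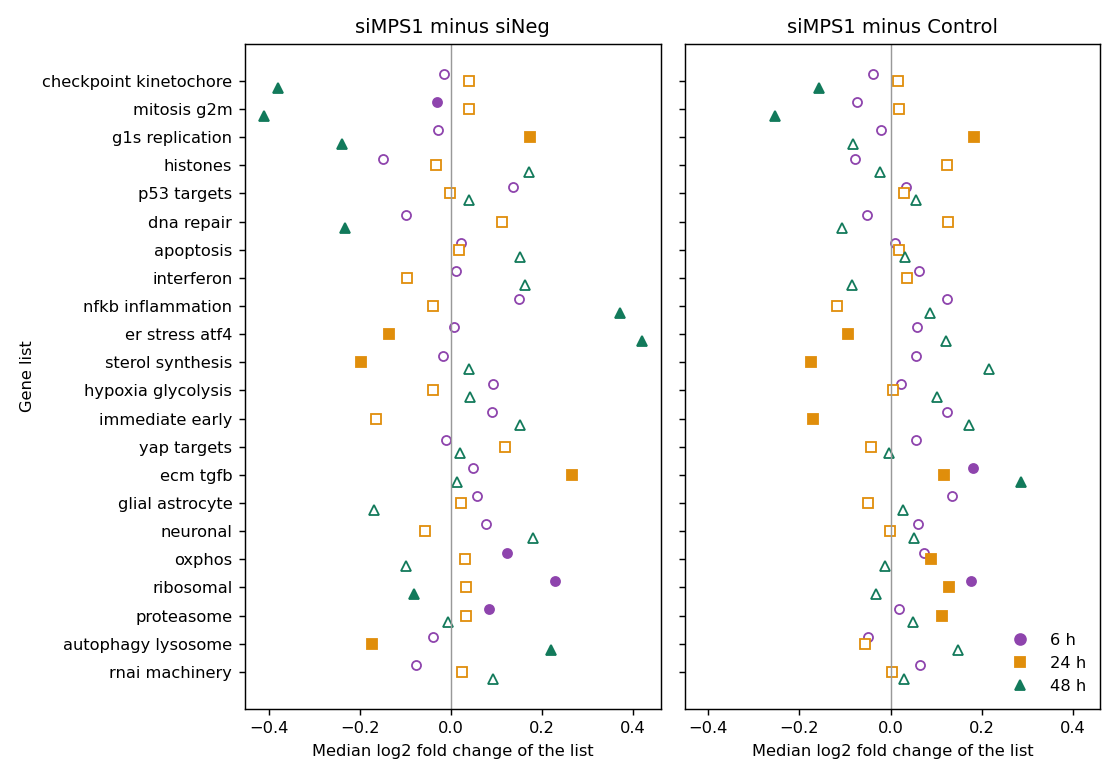
Median log2 fold change of each gene list in siMPS1 minus siNeg (left) and siMPS1 minus Control (right), with a symbol per time in h, filled where the list was called at the preset correlation. At 48 h the mitotic list had medians of -0.41 and -0.25, whereas the ribosomal list at 6 h, 0.23 and 0.18 as plotted, became 0.01 and -0.014 under quantile normalization.

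Matrix genes were called higher in siMPS1 than in Control at every time, although with an estimated correlation the calls at 6 and 24 h ended (adjusted p = 0.069 at both). These calls also ended when the probe sets of a gene were averaged, and the 6 h median turned to -0.017 under median centring. Matrix genes were higher than in siNeg at 24 h alone (adjusted p = 0.662 at 6 h and 0.974 at 48 h, medians 0.05 and 0.01), as siNeg was itself higher than Control at 6 and 48 h. At 48 h the collagen genes COL5A1, COL6A1 and COL4A2 rose by 0.79, 0.45 and 0.51 and SPARC, a matrix glycoprotein, by 0.44, although COL6A1 was at -0.15 when its probe sets were averaged. In this list 14 of 32 members rose and 1 fell (16 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.00105, and adjusted p = 0.0454 with an estimated correlation). The member that fell, named after its value was seen, was LOX, a collagen cross-linking enzyme, with -0.54. At 6 h 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them COL6A2 by 0.67, with a median of 0.18 and an adjusted p of 0.0115. At 24 h 10 rose and 2 fell (10 and 4 adjusted over the list alone, adjusted p = 0.0117), with COL4A1 at 0.81, COL5A1 at 0.80 and SPARC at 0.55, and with COL6A2 and TGFB1, the latter named after its value was seen, at -0.86 and -0.65.

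The ribosomal list was higher than Control at 6 h by a median of 0.18 (-0.014 under quantile normalization and -0.021 under median centring) and at 24 h by 0.13 (-0.0023 under quantile normalization), each with an adjusted p of 9.55e-05 and an adjusted p = 0.594 with an estimated correlation. At 24 h 7 other lists were called against Control besides it, and none of the 8 kept its call with an estimated correlation. Replication genes such as MCM6 (0.79) and TYMS (0.39) were up with an adjusted p of 0.00238 (adjusted p = 0.147 with an estimated correlation), and oxidative phosphorylation and proteasome genes were up with adjusted p of 0.000349 and 0.0115 (adjusted p = 0.127 and adjusted p = 0.247 with an estimated correlation). Sterol genes, with MSMO1 at -1.38, LSS at -0.56 and FASN at -0.50, ER stress genes, with PPP1R15A at -0.72, and immediate early genes, with FOSB at -1.60, were down. Their adjusted p were 0.00594, 0.0298 and 0.0156, and with an estimated correlation adjusted p = 0.069, adjusted p = 0.163 and adjusted p = 0.077. Leaving out Control 24 h replicate 1 or siMPS1 24 h replicate 1 ended the calls of ER stress and immediate early genes, with adjusted p up to 0.0599 and 0.065, and leaving out siMPS1 24 h replicate 2 ended that of ER stress genes.

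Genes called between siMPS1 and Control numbered 1297 at 6 h (727 higher, 570 lower), 992 at 24 h (429 and 563) and 2153 at 48 h (1195 and 958). The split depended on scaling. Under quantile normalization it was 593 higher and 577 lower at 6 h (50.7% higher instead of 56.1%). It was 50.3% higher at 24 h instead of 43.2%, and 53.5% at 48 h instead of 55.5%. Under median centring it was 227 higher and 2036 lower at 6 h (10% higher), 68.5% higher at 24 h, and 863 higher and 1108 lower at 48 h. Centring used array medians over all probe sets but the controls, including the dim ones left out of the tests. It moved the median of the tested genes at 6 h from 0.038 to -0.159, and the splits under centring carry such shifts. The count at 6 h was 618 and 503 without Control 6 h replicates 1 and 2 in turn and 471 without siMPS1 6 h replicate 2. At 24 h it was 523 and 448 without Control 24 h replicates 1 and 2, 558 without siMPS1 24 h replicate 2 and 598 with only the compared groups in the fit, and at 48 h it was 1427 without Control 48 h replicate 2 and 1415 without siMPS1 48 h replicate 2.

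Averaged over the times, MSMO1 fell by 1.22 against siNeg (SE 0.04, adjusted p = 2.21e-12), and ADORA2B (-1.29, adjusted p = 2.12e-11), SEPTIN10 (-1.200, adjusted p = 3.11e-11), TTK (-1.87, adjusted p = 4.09e-09) and HOXB3 (-1.47) fell too. IL1RAP, HDAC7, FGF1, TAOK1 and PADI1 rose by 1.01, 0.998, 0.99, 0.95 and 0.89, although for IL1RAP and FGF1 the only other probe set past the filter had the opposite sign. The checkpoint list had 0 of 30 members up and 13 down (0 and 15 adjusted over the list alone, adjusted p = 2.7e-05, and adjusted p = 0.00507 with an estimated correlation), with PLK1 at -0.76, SPC25 at -0.38 and BIRC5, or survivin, at -0.31. The mitotic list had 2 of 43 up and 22 down (3 and 23 adjusted over the list alone, adjusted p = 3.15e-06, and adjusted p = 0.00476 with an estimated correlation), with CCNB2 at -0.80 and CCNB1 at -0.46, and with MKI67 (0.27) and CDC25B (0.36), named after their values were seen, going up. In all 1940 genes were called, 1011 higher and 929 lower, and an average of 6 and 24 h alone, chosen after seeing the data, called 1119.

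Genes lower at all times against both controls numbered 37, and those higher numbered 3. Besides TTK, the former included ADORA2B, MSMO1, SEPTIN10, CHMP2B, JPT1 and VAPA, as well as CCNE2 (-0.97, -0.75 and -1.28 against siNeg at 6, 24 and 48 h). Others, named after their values were seen, were SOAT1, which esterifies cholesterol (-0.82, -1.09 and -0.69), IL6ST, a cytokine receptor subunit (-0.53, -0.95 and -0.76), the ubiquitin ligase gene SMURF2 (-0.64, -0.95 and -0.80) and CHUK, a kinase of NF-kB signalling (-0.63, -0.72 and -0.65). The 3 higher genes, named after their values were seen, were TUBA4A, an alpha-tubulin (0.36, 0.35 and 0.39), PNRC2 (0.24, 0.53 and 0.38) and S100A2 (0.27, 0.30 and 0.70). Against siNeg alone 56 genes were lower and 12 higher at all times, against 2.6 and 2.18 for independent calls. In 50 simulations without change the highest number against both controls was 0, but such simulations call almost no genes and do not test these counts. The count of 37 was 20 and 21 without siNeg 6 h replicates 1 and 2 in turn and 19 without siMPS1 6 h replicate 2. The count of 3 was 5 with the lowest 60% of probe sets left out or with probe sets averaged, 0 without the intensity trend, 0 under median centring, and 7 at 6 and 24 h alone. It was 0 without Control 6 h replicate 2, siNeg 6 h replicate 1, siMPS1 6 h replicate 2 or siMPS1 24 h replicate 2, and 1 without siNeg 6 h replicate 2, Control 24 h replicate 1 or siNeg 24 h replicate 1.

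Cells given the negative-control siRNA differed from Control in few genes at 24 h and in more at 6 and 48 h. The dap poly(A) spike differed between these groups as well. Its signal was 6.57 in siNeg against 7.21 in Control at 6 h, 7.12 against 6.76 at 24 h and 5.56 against 7.46 at 48 h. An effect of transfection could thus not be told apart from a difference in sample preparation. At 6 h the nascent polypeptide pseudogene NACA4P (1.96, SE 0.19, adjusted p = 4.75e-05), RUNX1-IT1, HIVEP3, PKD1P1 and GIT2 were higher in siNeg than in Control, the last 4 by 1.95, 1.81, 1.80 and 1.78. C21orf91, AKTIP, ZNF24, CTSZ (a lysosomal cathepsin) and the kinase gene CSNK1A1 were lower, by -0.87, -0.65, -0.57, -0.54 and -0.53. At 24 h ULBP2, a ligand of natural killer receptors, rose by 1.01, IMP3 by 0.71, RPL34 by 0.64, the interferon gamma receptor gene IFNGR2 by 0.60 and PAIP1 by 0.56, while SSBP3, SKI, the kinase gene AKT1, SLIT2 and DCTN1 changed by -1.44, -0.74, -0.70, -0.67 and -0.65. In ZNF24, CSNK1A1 and PAIP1, 1 other probe set past the filter had the opposite sign. Interferon-induced genes passed no test between siNeg and Control (adjusted p = 0.917, 0.186 and 0.153 at 6, 24 and 48 h), nor did genes of the RNA interference machinery (adjusted p = 0.125, 0.841 and 0.92).

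Among lists at 6 h, matrix genes were higher in siNeg than in Control by a median of 0.14 that turned to -0.0092 under median centring. Of 32 members 4 rose and 0 fell (9 and 0 adjusted over the list alone), with COL6A2 at 0.60, COL6A1 at 0.29, COL5A1 at 0.33 and TGFB1 at 0.75. The adjusted p was 0.00392 (adjusted p = 0.0369 with an estimated correlation) and ranged from 0.000195 to 0.204 over 11 alternatives, the call ending when probe sets were averaged or arrays median-centred. Oxidative phosphorylation, ribosomal and proteasome genes were called down at 6 h with medians from -0.08 to -0.07, and with an estimated correlation had adjusted p = 0.173, adjusted p = 0.753 and adjusted p = 0.109. The same lists and the autophagy list were called up at 24 h with medians from 0.05 to 0.07, and with an estimated correlation had adjusted p = 0.186, adjusted p = 0.602, adjusted p = 0.146 and adjusted p = 0.115. Each of these 7 calls ended under quantile normalization. Leaving out Control 6 h replicate 2 or siNeg 6 h replicate 1 ended the ribosomal call at 6 h (adjusted p up to 0.141), leaving out Control 24 h replicate 1 that at 24 h (adjusted p = 0.0976), and leaving out Control 24 h replicate 1, siNeg 24 h replicate 1 or siMPS1 6 h replicate 1 that of autophagy genes (adjusted p up to 0.295).

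At 48 h, siNeg cells had less HMOX1 than Control cells, by a log2 fold change of -1.66 (SE 0.08, adjusted p = 2.38e-10), and less CALB1, a calcium buffer, by -1.46 (adjusted p = 1.45e-08). RASSF8, HLA-DOA and C6orf15 were lower by -1.75, -1.61 and -1.59, and IGFBP4, the kinase gene SRC, HOOK2, DHRS3 and ZNF335 were higher by 1.77, 1.72, 1.72, 1.46 and 1.43. Genes of ER stress were lower in siNeg, with 1 of 33 up and 16 down (2 and 20 adjusted over the list alone, median -0.27, adjusted p = 5.82e-09, and adjusted p = 0.00877 with an estimated correlation), with ATF3, DDIT3, HERPUD1 and DNAJB9 at -0.98, -0.78, -0.65 and -0.58 and SLC7A5, named after its value was seen, at 0.23. Genes of NF-kB and inflammation were lower, with 2 of 24 up and 6 down (2 and 12 adjusted over the list alone, adjusted p = 0.00111, and adjusted p = 0.0303 with an estimated correlation). MMP1, TNFAIP3, an NF-kB inhibitor, and PTX3 were at -0.90, -0.52 and -0.65, while PLAU and, named after its value was seen, TNFAIP2 were at 0.43 and 0.58. Autophagy genes were lower, with 0 of 27 up and 6 down (1 and 7 adjusted over the list alone, adjusted p = 0.00262, and adjusted p = 0.0369 with an estimated correlation), including WIPI1 at -0.75.

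Cell cycle and matrix genes were higher in siNeg than in Control at 48 h. The mitotic list had 12 of 43 members up and 0 down (15 and 0 adjusted over the list alone, median 0.17, adjusted p = 1.91e-05, and adjusted p = 0.00877 with an estimated correlation), with KIF4A, KIF18B, ESPL1 and KIF20A at 0.49, 0.68, 0.65 and 0.61. The checkpoint list had 9 of 30 up and 0 down (median 0.17, adjusted p = 0.000491, and adjusted p = 0.0214 with an estimated correlation), with PLK1 at 1.14 and BUB1B at 0.65. Replication genes had 10 of 41 up and 0 down (12 and 0 adjusted over the list alone, median 0.16, adjusted p = 0.00011, and adjusted p = 0.0579 with an estimated correlation), with MCM2 and MCM7 at 0.43 and 0.47. Matrix genes had 12 of 32 up and 1 down (13 and 1 adjusted over the list alone, median 0.24, adjusted p = 4.01e-05, and adjusted p = 0.00877 with an estimated correlation), with COL6A2, COL5A1, MMP2 and COL4A2 at 0.99, 0.79, 0.78 and 0.62 and LOX, named after its value was seen, at -0.70. In the siNeg arrays of 48 h the signals of the dap and lys poly(A) spikes, added to the RNA before labelling, were 5.56 and 2.90 on the log2 scale, against 7.46 and 4.40 in Control.

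Genes called between siNeg and Control numbered 299 at 6 h (222 higher, 77 lower), 73 at 24 h (36 and 37) and 1012 at 48 h (534 and 478). Under quantile normalization 69.4% of the called genes were higher at 6 h instead of 74.2%, and 47.7% at 24 h instead of 49.3%. Under median centring, which moved the median of all genes at 6 h to -0.128, they were 11.5% at 6 h and 86.6% at 24 h. The count at 6 h was 81 and 121 without Control 6 h replicates 1 and 2 in turn and 107 and 61 without the siNeg arrays, and at 24 h it was 6 and 4 without the Control arrays and 8 and 9 without the siNeg arrays of that time. It was 43 and 44 at 24 h without the Control arrays of 6 h and 46 without either siNeg array of 6 h. At 48 h it was 507 and 612 without Control 48 h replicates 1 and 2 and 440 without siNeg 48 h replicate 1.

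**Figure D4:**
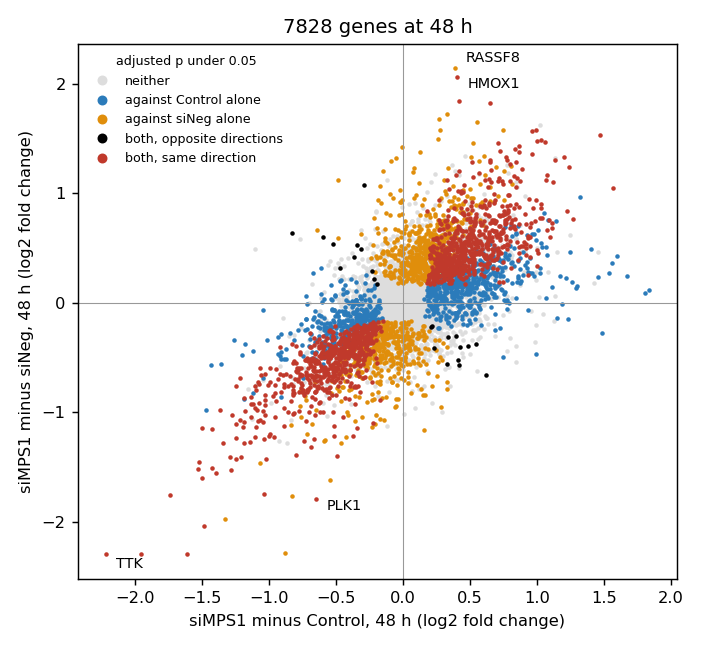
Log2 fold change of siMPS1 minus Control (horizontal) against siMPS1 minus siNeg (vertical) at 48 h, with a point for each of 7828 genes, coloured by the comparison in which it was called. TTK fell against both (-2.22 and -2.30), whereas RASSF8 and HMOX1 had 0.39 and 0.40 against Control and 2.14 and 2.06 against siNeg.

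HMOX1, RASSF8 and DDIT3 were among the genes that moved in opposite directions from Control to siNeg and from siNeg to siMPS1 at 48 h. Such genes numbered 518, or 22.7% of those called between siMPS1 and siNeg, against 75.2 and 71.8 for the 2 directions if calls were independent. The 50 simulations without change gave at most 1, but they call almost no genes and do not measure what shared siNeg arrays add. Of the 518, 377 were not called between siMPS1 and Control, 221 of them higher and 156 lower in siMPS1 than in siNeg. That number was 242 without Control 48 h replicate 1 and 189 without siNeg 48 h replicate 1. The correlation of the 2 fold changes across genes, which are not independent replicates, was -0.476 (simulated -0.498), with a covariance of -0.0602 (simulated -0.0189).

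Calls against siNeg and against Control, which share the siMPS1 arrays, overlapped. The same direction was called for 336 genes at 6 h (55.7% of those called against siNeg), 483 at 24 h (56.4%) and 1293 at 48 h (56.6%), TTK, MSMO1, ADORA2B and SEPTIN10 being among them at every time. Independent calls would give 25.1 higher and 24.2 lower genes at 6 h, 22 and 32.7 at 24 h, and 188 and 129 at 48 h. The simulations gave at most 1 at any time, but they hold no change, call almost no genes and so do not test this overlap. The correlations across genes were 0.63, 0.693 and 0.674 (simulated 0.5, 0.497 and 0.503), and the covariances 0.0596, 0.0622 and 0.102 (simulated 0.0191, 0.0191 and 0.0192). With 2 siMPS1 arrays per time these could not be divided between the comparisons with 2 in each part, so part of the overlap may stem from the shared siMPS1 arrays. Between times, which share none, the same direction was called for 134 genes at 6 and 24 h (14 opposite), 372 at 24 and 48 h (86 opposite) and 151 at 6 and 48 h (77 opposite), with correlations of 0.19, 0.218 and 0.0693.

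The response to siMPS1 differed between times. ABCA1 and SSR3 were among the 289 genes whose change against siNeg differed between 6 and 24 h, by 1.84 and -1.37, and HMOX1 and TAF9B among the 1234 that differed between 24 and 48 h, by 2.58 and -2.45. The count of 289 was 132 and 161 without siNeg 6 h replicates 1 and 2 in turn, 126 and 152 without siNeg 24 h replicates 1 and 2, 159 without siMPS1 6 h replicate 2 and 136 without the intensity trend. In untransfected cells the median of all genes rose by 0.12 from 6 to 24 h, and 2125 genes were called higher and 1247 lower. These were 1793 and 1430 after quantile normalization, and 1296 and 1937 after median centring. From 24 to 48 h the median changed by -0.05, with 626 genes higher and 907 lower. These were 690 and 772 after quantile normalization, and 1420 and 396 after median centring. The second count of 1533 genes was 976 and 805 without Control 24 h replicates 1 and 2 and 976 and 928 without those of 48 h. TTK rose by 1.44 in Control from 6 to 24 h (adjusted p = 1.83e-05) and changed by -0.23 from 24 to 48 h (adjusted p = 0.476).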

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

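The tests of explanations in this part were chosen after the results were seen, except the comparison of the average with other splits of the arrays, which was chosen before. The differences between successive times, quantile normalization and median centring were among the contrasts and alternatives chosen before.

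More genes were lower than higher in siMPS1 at all times against both controls, 37 against 3, with TTK, MSMO1 and ADORA2B among the former. The 37 were chosen as lower than siNeg too, so a response equal in siNeg was left out by selection. For the 83 genes lower than Control at all times, the median change from Control was -0.048 in siNeg and -0.586 in siMPS1. This ratio of 0.0819 was lowered by selection, since the 83 were chosen by their fall in siMPS1. The small siNeg median argues against a response to any siRNA as the whole of their median fall, but leaves a part open. Of the 83, 24 were also called lower in siNeg than in Control at 1 or more times. Over all 7828 genes 77, 37 and 478 were so called at 6, 24 and 48 h, so such calls were more frequent among the 83. The shared Control arrays may add to this. Poorer RNA in the siMPS1 samples might lower such genes, and 2 of 4 siMPS1 arrays of 6 and 24 h had an ACTB 3' to 5' ratio above all other arrays of their time, which does not decide. Both were at 24 h (0.4265 and 0.4269, against 0.4127 and 0.4005 in siNeg), while at 6 h the ratio was 0.2576 and 0.2494 in siMPS1, under the 0.2952 and 0.2752 in siNeg. Pairing of the siRNA with other mRNAs was not tested, since no sequences were used.

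The siNeg arrays of 48 h differed from both other groups in 377 genes such as RASSF8 that were not called between siMPS1 and Control. A missing call does not show that siMPS1 and Control were equal. More genes, 1293, were called in the same direction in siMPS1 against both controls at 48 h, so siNeg was not the only group apart. The rest concerns the 377. Shared siNeg arrays could produce such genes. Simulations without change gave at most 1, but they call almost no genes, so this count does not decide. Across genes the 2 fold changes had a correlation of -0.476 (simulated -0.498) and a covariance of -0.0602 (simulated -0.0189). Scaling was excluded, with 370 genes left under quantile normalization. Cells closer to their 24 h state could not be told apart from other causes, as the correlations across genes were 0.112 and 0.114. A difference in RNA handling or labelling may contribute and was not tested. The siNeg arrays of 48 h also had the lowest mean dap (5.56), lys (2.90) and 18S rRNA (9.47) signals and ACTB ratio (0.117) of all groups. How the arrays were labelled in batches is not given in the sources used here.

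Mitotic and checkpoint genes such as CCNB2 and BUB3 were lower in siMPS1 at 48 h against both controls. Scaling was excluded, since the highest adjusted p of these lists against Control under quantile normalization or median centring was 0.00344. A 3' bias of the siMPS1 arrays may contribute, and with a mean ACTB log2 ratio of 0.895 in these arrays and no others it could not be told apart from MPS1 loss. Against a position further along the change of untransfected cells from 24 to 48 h, the correlations with that change were -0.248 and -0.223 across the members of these lists. Across all genes they were -0.205 and -0.191, but siNeg also leaned towards the 24 h state (correlations of 0.112 and 0.114), so part may be common to both transfected groups. Matrix genes fell in Control over that time (median -0.30) and were higher in siMPS1 than in Control (median 0.29). They were higher in siNeg as well (median 0.24), so they do not bear on siMPS1 alone. A position further along could still not be told apart, since the mitotic list itself fell in Control over that time (median -0.17, adjusted p = 0.00653 with an estimated correlation).

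For the average over the times, 1 of 100 splits of the arrays, the real one, gave as many as 1940 genes, and the highest other gave 1450. That one was among 3 splits that kept the arrays of each group together, while splits that parted a group reached 1109. Parting a group puts treatment differences into the spread and lowers the count (median of all other splits 0). The real split is thus comparable only with these 3, and 1 of 100 is not a chance level.

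From 6 to 24 h the siMPS1 minus siNeg difference changed in 289 genes. It rose by 1.98 for ATP5MC2P1, 1.84 for ABCA1, 1.59 for MED12, 1.54 for SIPA1L3 and 1.47 for FGF1. The change was -1.82 for ZNF747, -1.72 for INAVA, -1.68 for KLHL12, -1.37 for SSR3 and -1.26 for CCL2. In MED12 and SIPA1L3, 1 other probe set past the filter had the opposite sign. List medians changed by 0.12 for mitotic, 0.15 for replication, 0.25 for DNA repair and 0.24 for matrix genes, and by -0.17 for ER stress, -0.20 for immediate early and -0.14 for autophagy genes. They changed by -0.12 for sterol, -0.10 for hypoxia, -0.21 for ribosomal and -0.071 for proteasome genes, which with an estimated correlation had adjusted p = 0.0712, adjusted p = 0.272, adjusted p = 0.343 and adjusted p = 0.229.

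From 24 to 48 h it changed in 1234 genes. It rose by 2.72 for RASSF8, 2.66 for RHOBTB2, 2.58 for HMOX1, 2.53 for FHL3 and 2.31 for CPEB1. The change was -2.45 for TAF9B, -2.34 for HTR4, -2.27 for PTMS, -2.07 for LGR5 and -1.92 for DCAKD, with 1 of 2 other probe sets of TAF9B past the filter going the opposite way. List medians changed by -0.47 for checkpoint, -0.38 for mitotic, -0.46 for replication, -0.27 for DNA repair and -0.17 for matrix genes, and by 0.25 for NF-kB, 0.50 for ER stress, 0.28 for sterol, 0.25 for immediate early and 0.39 for autophagy genes. They changed by -0.13 for oxidative phosphorylation and -0.16 for ribosomal genes, which with an estimated correlation had adjusted p = 0.167 and adjusted p = 0.503.

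The ACTB 3' to 5' log2 ratio was 0.41 in siNeg at 24 h, 0.43 in siMPS1 at 24 h, 0.90 in siMPS1 at 48 h and 0.12 in siNeg at 48 h, against 0.149 to 0.333 in Control arrays. That of GAPDH was 0.086 in siMPS1 at 24 h and 0.29 at 48 h. The 18S rRNA signal was 10.36 in siMPS1 at 6 h, 11.15 in siNeg at 24 h, 10.36 in siMPS1 at 24 h and 11.13 in siMPS1 at 48 h, but 9.47 in siNeg at 48 h, against 10.12 to 10.22 in Control arrays, and the Alu signal was 12.96 in siMPS1 at 6 h. Signals below those of all Control arrays were also seen for the dap spike in siNeg at 6 h (6.57), siMPS1 at 6 h (6.27) and siNeg at 48 h (5.56), for the lys spike in siNeg at 48 h (2.90) and for the bioB spike in siMPS1 at 24 h (6.51).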

How the results depend on the processing

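With 2 arrays per group, leaving out an array leaves an arm with 1 array, which is then assumed to vary like the other groups. The TTK call kept its direction and passed in every setting, and without 1 array its log2 fold change ran from -1.55 to -1.31, -2.13 to -1.64 and -2.56 to -2.04 at 6, 24 and 48 h. Elsewhere the cause of a change was not tested. Counts below are in the order siMPS1 minus siNeg, siNeg minus Control and siMPS1 minus Control unless named.

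Leaving out 1 array gave 80 to 684, 361 to 864 and 1655 to 2359 genes for siMPS1 minus siNeg at 6, 24 and 48 h, 61 to 312, 4 to 108 and 440 to 1047 for siNeg minus Control, and 471 to 1420, 448 to 1029 and 1415 to 2202 for siMPS1 minus Control. It gave 126 to 330 for the change from 6 to 24 h, 805 to 1592 for Control from 24 to 48 h, 19 to 38 genes lower and 0 to 4 higher at all times, 189 to 391 for the 377 genes set apart by siNeg, and 2 to 4 lists for siNeg minus Control at 24 h.

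Quantile normalization left 2 lists for siMPS1 minus siNeg at 6 h, 1 for siNeg minus Control at 6 h and 0 at 24 h, and turned the ribosomal median against Control to -0.014 at 6 h and -0.0023 at 24 h. Median centring, with array medians taken over the dim probe sets too, gave 1155 and 134 genes for siNeg minus Control at 6 and 24 h. It gave 2263 for siMPS1 minus Control at 6 h and 0 genes higher at all times. It turned the matrix median to -0.0092 (siNeg minus Control) and -0.017 (siMPS1 minus Control) and the ribosomal one to -0.021 (siMPS1 minus Control) at 6 h.

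Without a filter 388 genes were called for siMPS1 minus siNeg at 6 h, and 196 and 42 for siNeg minus Control at 6 and 24 h. With the lowest 60% left out the last was 138 and 5 genes were higher at all times. With probe sets averaged it was 111, 5 genes were higher at all times, 2 lists were called for siNeg minus Control at 6 h, and RPL7 (siNeg minus Control, 6 h), RPL38 and COL6A1 (siMPS1 minus Control, 24 and 48 h) turned to 0.00049, -0.12 and -0.15. Without the intensity trend there were 169 genes for siMPS1 minus siNeg at 6 h, 145 and 3 for siNeg minus Control at 6 and 24 h, 136 for the change from 6 to 24 h and 0 higher at all times.

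A replicate block, which pairs arrays by number, gave 35 genes for siNeg minus Control at 24 h and 998 for Control from 24 to 48 h. Residual correlations at one time ran from -0.0876 to 0.103 over 9 pairs of groups, so no strong effect shared by equal numbers was seen. Whether the numbers pair samples is not given in the sources used here. An estimated correlation left 0 lists for siMPS1 minus siNeg at 6 h, and 1 and 0 for siNeg minus Control at 6 and 24 h. With only the compared groups, 24 h gave 502, 135 and 598 genes.

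A fold change of at least 2 as well left 24, 47 and 169 genes for siMPS1 minus siNeg at 6, 24 and 48 h, 24, 2 and 49 for siNeg minus Control, 58, 41 and 125 for siMPS1 minus Control, 11 for the average, 32 and 165 for the changes between times, and 557 and 76 for Control. Counting probe sets gave 506 and 162 for siNeg minus Control at 6 and 24 h and 1869 for the change from 24 to 48 h. Without 48 h the average had 1119 genes and 7 were higher at all times, and 336, 483 and 1293 of the siMPS1 minus siNeg genes were also called against Control.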

Other observations

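Untransfected U251 cells changed strongly between 6 and 24 h, over a median rise of all genes of 0.12. All 43 measured mitotic genes rose, by a median of 1.48, among them the cyclin genes CCNB1 (1.99) and CCNB2 (2.03), the kinase gene AURKA (2.16) and the spindle gene DLGAP5 (2.49), and 24 of 30 checkpoint genes rose and 2 fell, with CENPF at 2.21 and CDC20, an activator of mitotic exit, at 2.04. YAP targets fell, 13 of 21 with 0 rising, with ANKRD1 at -2.74 and IGFBP3, which binds insulin-like growth factors, at -3.15. Matrix genes (23 of 32 down and 1 up, COL4A1 at -1.68), NF-kB genes (12 of 24 down and 4 up) and immediate early genes (17 of 29 down and 4 up, the growth factor gene HBEGF at -3.28 and EGR1 at -2.04) fell as well. Replication genes were called down and ER stress, sterol and proteasome genes up, with adjusted p = 0.0767, adjusted p = 0.0593, adjusted p = 0.058 and adjusted p = 0.115 with an estimated correlation.

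From 24 to 48 h untransfected cells lost ER stress genes, 22 of 33 falling and 1 rising, with HERPUD1 at -1.11, ATF3 at -1.44 and DDIT3 at -0.98. Matrix genes (14 down and 2 up, COL6A2 at -1.29), immediate early genes (12 down and 1 up) and mitotic genes (15 down and 0 up, median -0.17) were lower. Genes of oxidative phosphorylation (20 of 38 up and 0 down, median 0.22) and replication (13 up and 2 down) were higher. Histone, interferon, neuronal and proteasome lists were called up, with adjusted p = 0.0641, adjusted p = 0.0739, adjusted p = 0.169 and adjusted p = 0.058 with an estimated correlation.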
